A study of Marmota monax with 7 samples.

How the data were processed

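Signals were measured on 7 membrane arrays made for human genes, each hybridised with total RNA of adult woodchuck liver at 0.1, 0.25, 0.5, 1, 2, 5 or 10 µg. All labels give 1 lot. The deposited values are spot intensities on a linear scale, whole and positive, for 5544 probes on each array. How the authors scanned the membranes, and whether they corrected background or scaled the intensities, is not given in the sources used here. From the values themselves, array medians ran from 1629 to 16520 and the lowest probe of each array stayed at 1252 or above, so neither a scaling between arrays nor a subtraction of background was seen. The unit of the scanner remains unknown. No value was at or below 0, so no floor was applied, and no probe was left out. Each array's maximum was reached by 1 probe, which shows no ceiling shared by several probes.

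Probes were named from the platform's annotation, in which 3346 probes had 1 gene symbol, 95 had several and 2103 had none. Names were taken only from probes with 1 symbol, which gave 3011 human genes, each represented by its probe of highest mean log2 signal. A table of woodchuck genes was not used here, because its identifiers are not those of the human annotation. The labels tie each array to its amount, and no sample was left out. Taking each array's lower percentile of 1 as background, the median was 1629 against 1329 at 0.1 µg and 16151.5 against 3550 at 10 µg, so small differences at the lower amounts rest on signals near the background.

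Computation used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Signals were log2 transformed. For each array the median, both quartiles, the upper percentiles of 90 and 99 and the dynamic range were set against log2 amount by Pearson and Spearman correlation with exact two-sided permutation over all 5040 pairings. For each probe, limma fitted a line of log2 signal on log2 amount over the 7 arrays with empirical Bayes moderation and Benjamini-Hochberg adjustment at 0.05. The fit was made without scaling and, separately, after subtraction of each array's median. A change of slope at 1 µg was fitted in the same way.

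Gene lists with at least 5 measured genes were tested on the median-centred slopes with limma's camera at a preset correlation of 0.01. Of 21 lists fixed before the data were examined, 20 were tested, and that of the mitochondrial genome had 0 measured genes. The level of each list on each array was its median percentile among the 3011 genes, set against 10000 random lists. The tests named so far and the rule for named genes were fixed in the same way. The rule allowed the 10 genes of highest mean signal, the 10 steepest rises and the 10 steepest falls among those past 0.05 in the median-centred fit, and in each list the 3 members of highest mean signal and the 3 of smallest p.

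Agreement of gene names with signal was checked with probes that share an accession or a symbol, using percentiles of mean log2 signal within each of 2 equal parts of the probe numbers. The reference was 2772 rotations of the names within each part. The split of the numbers at probe 2772 was chosen from the data, because the parts differed in median signal (25485.5 and 9241.5 at 10 µg). An exploratory shift of the names against the probes found no offset that stood out, and no probe was renamed.

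The scripts were tested on simulated data with noise drawn independently for each probe. In the slope and bend fits 50 probes were changed per size. Noise shared by the probes of an array was not simulated, so the rates found may not hold for the real arrays. In the slope fit on 5544 probes, 60.0% of slopes of 0.25, 64.0% of slopes of -0.25, 96.0% of slopes of 0.5 and 98.0% of slopes of 1 were found, with 3.05% false calls. The bend fit found 0% of changes of 0.5, 28.0% of changes of 1, 22.0% of changes of -1 and 78.0% of changes of 2. The list test found a shift of 0.25 in a list of 23 genes in 62.0% of draws, and 3.33% of unshifted lists had p under 0.05. Alternatives were other amount scales, a filter on dim probes, a variance trend, an added offset of 1973, leaving out each array, other scalings, an estimated correlation, the mean of a gene's probes and other places of the bend. Added after the data were seen were the check of names with its rotations, the test of slopes against 1, brightness classes ranked on 1 array, all tests of the observations other than reassigned amounts in both slope fits, centring within each part of the probe numbers, leaving out both 5 and 10 µg, and 2 further kinds of random list.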

Results

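Total RNA from the liver of adult woodchucks (Marmota monax), a rodent used as a model of hepatitis B infection, was hybridised to membrane arrays made for human genes. The labels describe the liver as normal and vary the amount of RNA, which was 0.1, 0.25, 0.5, 1, 2, 5 or 10 µg, with 1 array at each amount and 7 arrays in all. The series asks how the amount of RNA affects the signal when the RNA and the array come from different species. Amount was therefore a numeric covariate, and no test was made between a pair of amounts. Nothing in the labels says that the arrays held RNA of separate animals or separate preparations, so the p-values measure only the scatter of these 7 arrays about a line, and their number limits the precision. Each array gave a signal for 5544 probes, and the summed signal ran from 12951278 at 0.1 µg to 1309231092 at 10 µg.

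Gene names here are those of the array's annotation, and pairs of probes with the same name did not share their signal. Among 117 pairs of probes with the same sequence accession, the Spearman correlation of their signal percentiles was -0.0799, across pairs that are not independent replicates. That value lay within the range from -0.360 to 0.283 given by 2772 rotations of the names along the probe numbers (one-sided permutation p over the rotations 0.753). In 21 of these pairs at least 1 probe lay among the brightest 10%, and in 0 of the 21 did both (exact 95% binomial interval 0 to 16.1%). For 392 pairs with the same gene symbol the correlation was 0.0390 (p = 0.212), and for the 279 of them with different accessions it was 0.0805 (p = 0.101). Each gene named in the text is thus the brightest probe that the annotation assigns to that gene, and signals of different probes were not read as relative amounts of transcript. Probes of 1 accession stood at percentiles of 100 and 33.3 for HNRNPA1, 95.8 and 52.8 for ACTB, and 96.5 and 76.0 for GAPDH. Signals and slopes of the dimmer probes of such genes are not given here and may differ.

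**Figure D1:**
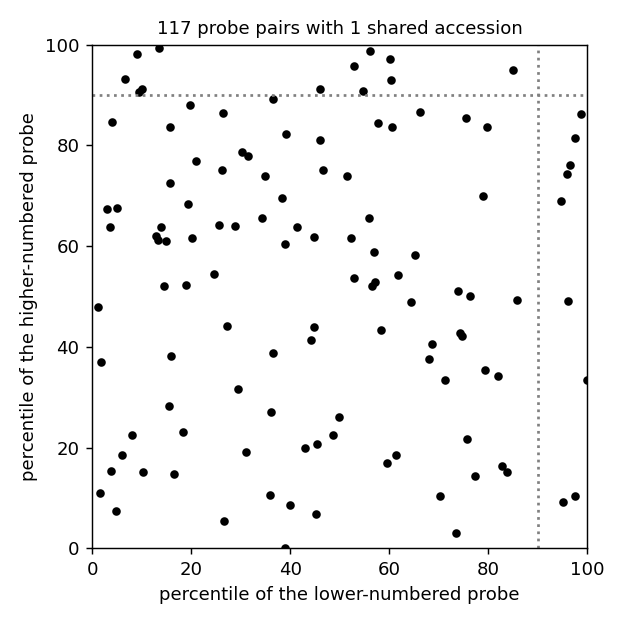
Each of the 117 points is a pair of probes that share an accession, placed by the signal percentile of the lower-numbered probe (horizontal axis) and of the higher-numbered probe (vertical axis), with dotted lines at the start of the brightest 10%. No pair lies in the upper right corner beyond both lines, and the correlation across pairs is -0.0799.

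The brighter of 2 probes of GAPDH, a glycolytic enzyme often used as a reference gene, read 12442 at 0.1 µg and 3491303 at 10 µg. This was a 281-fold difference for a 100-fold difference in RNA. The probe of APOB, the main protein of very-low-density lipoprotein made by hepatocytes, read 21355 and 6312172 (296-fold), and that of CYP2E1, a liver cytochrome P450, read 3418 and 495678 (145-fold). At the other end, the probe of MX1, an interferon-induced GTPase, read 1871 and 3680, and that of HMOX1, haem oxygenase 1, read 1689 and 4110. At 10 µg both lay near the background, as the lower percentile of 1 was 3550, and that percentile itself differed 2.67-fold between 0.1 and 10 µg. The median signal of the array was 1629 at 0.1 µg and 16151.5 at 10 µg (9.91-fold), with a higher value of 16520 at 5 µg. Between 0.1 and 10 µg the upper percentile of 99 differed 273-fold, and the lowest signal on the array 1.94-fold.

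Median log2 signal rose with log2 amount over the 7 arrays (Pearson r = 0.939, exact two-sided permutation p = 0.000397; Spearman rho = 0.964, exact permutation p = 0.00278). With the arrays of 0.1 and 10 µg left out r was 0.931. The upper percentile of 99 rose more closely with amount (r = 0.990, exact permutation p = 0.000198, the smallest that the 5040 pairings can give for r; rho = 1, exact permutation p = 0.000397). Over the 5 percentiles tested, Benjamini-Hochberg values were 0.000397 for each r and at most 0.00278 for rho. The dynamic range, taken as that percentile minus the median on the log2 scale, widened from 3.48 at 0.1 µg to 8.26 at 10 µg (r = 0.978, exact permutation p = 0.000397; rho = 1, exact permutation p = 0.000397; r = 0.983 without 0.1 and 10 µg). Background left in the signal narrows this range where the median lies near it. The median was 1629 against a lower percentile of 1 of 1329 at 0.1 µg, and 16151.5 against 3550 at 10 µg. The range was not computed after subtraction of background, so how much of the widening background accounts for is not known.

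**Figure D2:**
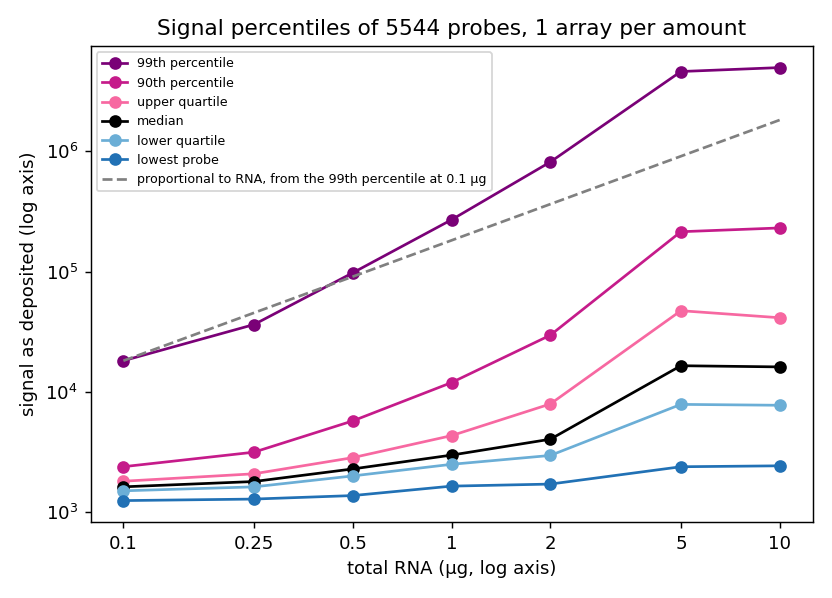
Percentiles of the signal of 5544 probes (vertical log axis, signal as deposited) against total RNA in µg (horizontal log axis), with 1 array per amount and a dashed line for signal in proportion to RNA. The median rises from 1629 to 16151.5 and the lowest probe stays between 1252 and 2435, with a step in the upper curves between 2 and 5 µg.

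Between successive arrays the largest step was the one from 2 to 5 µg. Across it the probe of GAPDH went from 346995 to 2216516, that of ACTB, cytoplasmic beta-actin, from 78017 to 723806, and that of APOE, an apolipoprotein secreted by the liver, from 296416 to 2559850. From 5 to 10 µg GAPDH read 3491303 at the larger amount, while ACTB read 654221 and APOE 1778502, both below their values at 5 µg. Over all probes the median step was 3.54-fold from 2 to 5 µg and 1.07-fold from 5 to 10 µg, and among the brightest 10% of probes the steps were 6.27-fold and 1.13-fold. With 1 array at each amount, these steps have no replicate check.

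Without any scaling of the arrays, the signal of nearly every named gene rose with the amount of RNA. The 10 genes of highest mean signal had slopes between 1.37 and 1.44 log2 units per doubling of RNA, where 1 is signal in proportion to RNA. They were HNRNPA1, a pre-mRNA binding protein (1.44 ± 0.10, SE over 7 arrays), PSMA5, a proteasome subunit (1.44 ± 0.10), BTBD1 (1.43 ± 0.09), FBXO34 (1.40 ± 0.09), KANK1 (1.40 ± 0.08), PRKAG2, a subunit of AMP-activated kinase (1.39 ± 0.10), RYBP (1.38 ± 0.09), GSTO1, a glutathione transferase (1.38 ± 0.10), GRM5, a glutamate receptor (1.37 ± 0.09), and CNRIP1 (1.37 ± 0.09). Each had a limma adjusted p of at most 1.76e-07. Limma borrows variance from the other probes, which share these arrays, while an exact permutation of 7 arrays cannot fall below 0.000198 for r. The limma values here and below are thus no measure of replication. Among the genes named here as falling against the array median, ADH6, an alcohol dehydrogenase (slope 0.07 ± 0.11, limma adjusted p = 0.516), COMMD6 (0.16 ± 0.08, 0.0772) and GABRE, a subunit of the GABA-A receptor (0.16 ± 0.08, 0.0651), did not pass.

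Over all probes, 5537 of 5544 rose and 0 fell (limma, Benjamini-Hochberg 0.05), and the lowest fitted slope was that of ADH6. The slope was steeper in brighter probes. With probes ranked on mean signal in 10 classes, its median was 0.28 in the dimmest class, 0.54 in class 5, 0.95 in class 9 and 1.28 in the brightest. This ranking shares its arrays with the slope, so classes were also ranked on the array of 0.1 µg and slopes fitted on the other 6, a setting added after the data were seen. The median slope was then 0.50 in the dimmest class, 0.63 in class 5, 0.98 in class 9 and 1.39 in the brightest. A slope above 1 was found for 382 of the 555 probes of the brightest class and for 0 probes outside it, and a slope below 1 for 3911 of all 5544 probes, in a test chosen after the data were seen. After subtraction of each array's median signal, 553 of these 555 probes had a slope above 1, with a median of 1.36. No other class was fitted after such a subtraction. Background left in the signal flattens the slopes of dim probes, so the 3911 slopes below 1 do not show a response under proportion. The rise of the slope with brightness has the same limit.

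**Figure D3:**
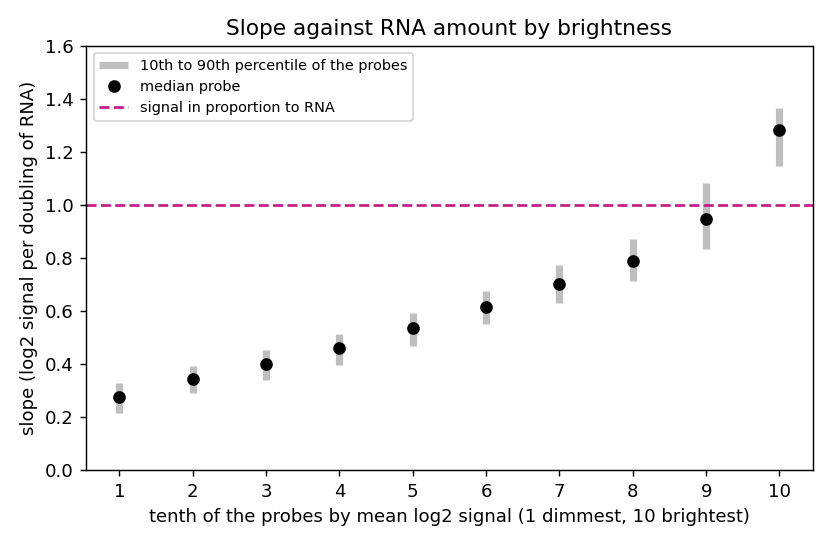
Slope of log2 signal per doubling of RNA (vertical axis) in 10 classes of the 5544 probes ranked on mean log2 signal (horizontal axis), with the median as a point and the range between the percentiles of 10 and 90 as a grey bar. The median rises from 0.28 in the dimmest class to 1.28 in the brightest, the only class with its median above the dashed line at 1.

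Relative to the median of the same array, the steepest rises were those of HNRNPA1 (0.88 ± 0.07 log2 units per doubling, SE over 7 arrays), PSMA5 (0.87 ± 0.08), BTBD1 (0.87 ± 0.06), ELF1, an ETS-family transcription factor (0.86 ± 0.05), PDE6G, a subunit of the photoreceptor phosphodiesterase (0.85 ± 0.09), PCDHA6, a protocadherin (0.85 ± 0.08), PRKY (0.85 ± 0.06), NR4A3, an orphan nuclear receptor (0.84 ± 0.06), FBXO34 (0.84 ± 0.06) and KANK1 (0.83 ± 0.05). Their limma adjusted p-values were at most 1.12e-05. The steepest falls were those of ADH6 (-0.49 ± 0.07), COMMD6 (-0.41 ± 0.07), GABRE (-0.40 ± 0.07), MX1 (-0.40 ± 0.07), ELF3, an epithelial ETS-family factor (-0.39 ± 0.08), THNSL1 (-0.39 ± 0.07), RPL7A, a ribosomal protein (-0.38 ± 0.08), PYGO2 (-0.38 ± 0.07), TDRD3 (-0.38 ± 0.07) and IGFBP1, a liver-secreted binding protein of insulin-like growth factors (-0.38 ± 0.08). Their limma adjusted p-values were at most 0.00241. At 10 µg these 10 probes read from 2435 (GABRE, the lowest signal on the array) to 5008 (ADH6), below the lower quartile of 7753.5, so their slopes are those of signals near the background. ADH6 read 5848 on the array of 0.1 µg and 1665 on that of 0.25 µg, and without the array of 0.1 µg its slope was -0.36 (limma adjusted p = 0.00226).

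In this fit 1880 probes rose and 1713 fell. The calls differed by class of mean signal, a ranking that shares its arrays with the fit, since 555 of 555 probes of the dimmest class fell, 555 of 555 of the brightest rose, classes 1 to 5 held no rise and classes 6 to 10 no fall. Centred on the 75th percentile of each array instead, 856 probes rose and 3212 fell, and after division by the median absolute deviation 4 rose and 389 fell, with 383 of the 393 calls opposite in direction to the median-centred ones. No probe passed under quantile normalization (limma, 804 at an unadjusted p under 0.05) or cyclic loess (limma, 178).

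Lists of genes of liver functions, cell types and common cell machinery were compared with this background, in which 1160 of 3011 genes rose and 801 fell relative to the array median. Every direction given for a list or its members is relative to that median. The calls followed mean signal, a ranking that shares its arrays with the fit, and no list test matched on brightness was made. The rises and falls of a list thus cannot be told apart from the brightness of its probes. They were not read as a separate response to the amount. Of the 98 genes that the naming rule gave, 94 passed 0.05 with median centring, 81 with the 75th percentile (1 of them in the opposite direction) and 88 with centring in 2 parts of the probe numbers (0 opposite). With the median absolute deviation 38 passed, 37 of them in the opposite direction, and with quantile normalization or cyclic loess 0 passed by limma. The median slope of all genes was 0.05 with median centring and -0.17 with the 75th percentile, under which the median slope of every list except the reference genes, the proteasome and the ribosomal proteins was below 0.

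Among the lists of common cell machinery, the reference genes and the proteasome, whose probes were bright, had mostly rises, as had the ribosomal proteins described below. Of 11 cytoskeletal and common reference genes 8 rose and 1 fell with median centring, 6 rose and 2 fell with the 75th percentile, and 0 rose and 2 fell with the median absolute deviation. Those that rose with median centring, but not with the deviation, include LDHA, a subunit of lactate dehydrogenase (0.83 ± 0.05), ACTB (0.75 ± 0.06), GAPDH (0.73 ± 0.04) and VIM, the intermediate filament protein vimentin (0.55 ± 0.05). Of 18 proteasome genes 12 rose and 1 fell with median centring, 9 rose and 5 fell with the 75th percentile, and 0 rose and 4 fell with the deviation, with PSMA5 followed in median-centred slope by PSMA1 (0.81 ± 0.07), PSME3 (0.79 ± 0.06) and PSMB7 (0.74 ± 0.07). Neither list passed against the other genes by limma's camera test with a preset correlation of 0.01, with adjusted p = 0.0636 for the reference genes and 0.106 for the proteasome. With an estimated correlation the adjusted p was 0.845 for each. The reference list alone passed without the 0.1 µg array (camera adjusted p = 0.0432), and both passed without 5 and 10 µg (0.0322 each), an alternative chosen after the data were seen.

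Ribosomal protein genes had 7 rises and 2 falls among 11 (0 and 1 with the median absolute deviation, 3 and 4 with the 75th percentile), with RPL10A at 0.79 ± 0.06, RPL28 at 0.71 ± 0.08 and RPL32P18, named as a pseudogene, at 0.64 ± 0.04. Nuclear genes of the respiratory chain and ATP synthase had 8 rises and 7 falls among 19, with ATP5MC3 at 0.62 ± 0.05 and COX6C at 0.51 ± 0.05. The counts for this list were 2 and 8 with the 75th percentile, 5 and 3 with centring in 2 parts of the probe numbers, and 0 and 0 with the deviation. Translation factors had 2 rises and 4 falls among 13 (1 and 8 with the 75th percentile). EIF4A1, an RNA helicase, stood at 0.76 ± 0.05, and EIF2AK2, an interferon-induced kinase that phosphorylates an initiation factor, at -0.27 ± 0.05. EIF2B2 did not pass (0.42 ± 0.17, limma adjusted p = 0.0526). Its probe read 6196 at 2 µg, 363515 at 5 µg and 28936 at 10 µg, so the array of 5 µg stood far above both neighbours.

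Liver lists held rises and falls together with median centring, while with the median absolute deviation 0 members of these lists rose. Hepatocyte secreted proteins had 10 rises and 6 falls among 23 (6 and 12 with the 75th percentile), from APOB (0.79 ± 0.06), APOE (0.72 ± 0.07) and ITIH3, a plasma protease inhibitor heavy chain (0.60 ± 0.05), to IGFBP1. Complement and coagulation genes had 10 and 2 among 17 but 1 and 5 with the 75th percentile, under which coagulation factor F10 (0.32 ± 0.06) and plasminogen, PLG (0.28 ± 0.05), did not pass and C5 (0.43 ± 0.05) did. Acute phase proteins had 3 and 1 among 5, but 0 and 2 with the 75th percentile and 1 and 0 with centring in 2 parts of the probe numbers. The fibrinogen chain FGG (0.23 ± 0.07) did not pass with the 75th percentile, and the chain FGB (0.16 ± 0.05) passed with neither and turned to -0.06 with the 75th percentile, while SAA1, serum amyloid A (-0.20 ± 0.05), did not pass with centring in parts. Xenobiotic metabolism had 13 and 5 among 25 (5 and 11 with the 75th percentile), including GSTO1 (0.81 ± 0.09), CYP3A7 (0.74 ± 0.07), ADH5 (0.70 ± 0.07) and CYP2E1 (0.65 ± 0.05). Amino acid and urea metabolism had 10 and 8 among 30 (6 and 14 with the 75th percentile), glucose metabolism 12 and 2 among 20 (4 and 7), and lipid, cholesterol and bile acid metabolism 8 and 3 among 23 (3 and 13). From these came GLDC of glycine cleavage (0.63 ± 0.06), FAH of tyrosine breakdown (0.60 ± 0.07), TKT, transketolase (0.75 ± 0.06), and CYP27A1, a sterol hydroxylase of bile acid synthesis (0.77 ± 0.07). Centring in 2 parts of the probe numbers gave 11 and 5 for hepatocyte secreted proteins, 6 and 3 for complement and coagulation and 7 and 4 for xenobiotic metabolism. For amino acid, glucose and lipid metabolism it gave 12 and 8, 8 and 3, and 9 and 7.

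Most lists of other cells of the liver also held rises and falls with median centring, while with the median absolute deviation 1 macrophage gene was the only one to rise. Endothelial genes had 9 rises and 4 falls among 17 (4 and 5 with the 75th percentile), led by EDNRB (0.72 ± 0.07), VWF, von Willebrand factor (0.67 ± 0.05), and ENG, endoglin (0.63 ± 0.06). Stellate cell, fibroblast and matrix genes had 9 and 4 among 18 (5 and 6), with FBN1, fibrillin 1, at 0.64 ± 0.05 and the collagen chain COL1A2 at 0.63 ± 0.08. Red cell genes had 7 and 0 among 11, but 2 and 4 with the 75th percentile and 4 and 2 with centring in 2 parts of the probe numbers, with the transcription factor GATA1 at 0.44 ± 0.05. Lymphocyte genes had 6 and 2 among 12 (1 and 4 with the 75th percentile), with IL2RG at 0.52 ± 0.05, and macrophage and Kupffer cell genes 5 and 2 among 13 (2 and 7), from LGMN, a lysosomal protease (0.70 ± 0.06), to HMOX1 (-0.36 ± 0.07). Bile duct epithelium had 1 and 2 among 7 (1 and 6 with the 75th percentile), with the keratin KRT19 at 0.38 ± 0.05 and SOX9 at -0.17 ± 0.06. Of the lists for tissues other than liver, striated muscle had 4 and 2 among 11 (2 and 6), with CSRP3 at 0.77 ± 0.06 and the cardiac regulator PLN at 0.81 ± 0.08. Neuron and glia had 4 and 1 among 17 (3 and 10 with the 75th percentile), with the neuronal enolase ENO2 at 0.74 ± 0.06.

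Over the 20 lists tested, 0 passed 0.05 by camera (2 at an unadjusted p under 0.05), and 0 with an estimated correlation (0 at an unadjusted p under 0.05). For acute phase proteins, the respiratory chain, translation factors and macrophages, the median and mean slope were above 0 while camera, which compares a list with all other genes, pointed down. Adjusted over the list alone, falls numbered 7 rather than 6 for hepatocyte secreted proteins, 2 rather than 1 for acute phase proteins, 7 rather than 8 for amino acid metabolism, 4 rather than 2 for glucose metabolism, 2 rather than 3 for lipid metabolism and 0 rather than 1 for neuron and glia, and other counts were equal.

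At 10 µg hepatocyte secreted proteins had a median signal percentile of 58.8 among the 3011 genes, above 80.8% of 10000 random lists of equal size. Complement and coagulation stood at 60.8, xenobiotic metabolism at 61.9, acute phase proteins at 65.2, glucose metabolism at 59.1, amino acid metabolism at 53.8 and lipid metabolism at 49.5. Striated muscle genes stood at 49.2 (above 47.8% of random lists) and neuron and glia at 51.4 (55.6%). No difference between lists was tested. The common reference genes stood at 88.2, above 99.9% of random lists, and the proteasome at 83.6, above 99.98%. These percentiles describe where the probes' signals lie and depend on how each probe binds, so they are not amounts of transcript. Over the 7 arrays the reference genes ranged from 82.7 to 88.8, above at least 99.4% of random lists, and the proteasome from 78.3 to 87.0, above at least 99.7%. With the mean of a gene's probes in place of the brightest probe, the reference genes stood above 98.4% at 10 µg but only 87.0% at 0.25 µg.

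Against 2772 rotations of the gene names along the probe numbers, which keep neighbouring probes together, the median percentile of the mean signal was 84.4 for the proteasome (two-sided permutation p over the rotations 0.00289) and 88.5 for the reference genes (p = 0.00577). Both had a Benjamini-Hochberg value of 0.0577, so 0 of 20 lists passed 0.05 (2 at an unadjusted p under 0.05). The rotations were added after these lists were seen to stand high. Ribosomal proteins stood at 73.4 at 10 µg, above 95.5% of random lists, and bile duct epithelium at 42.5.

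**Figure D4:**
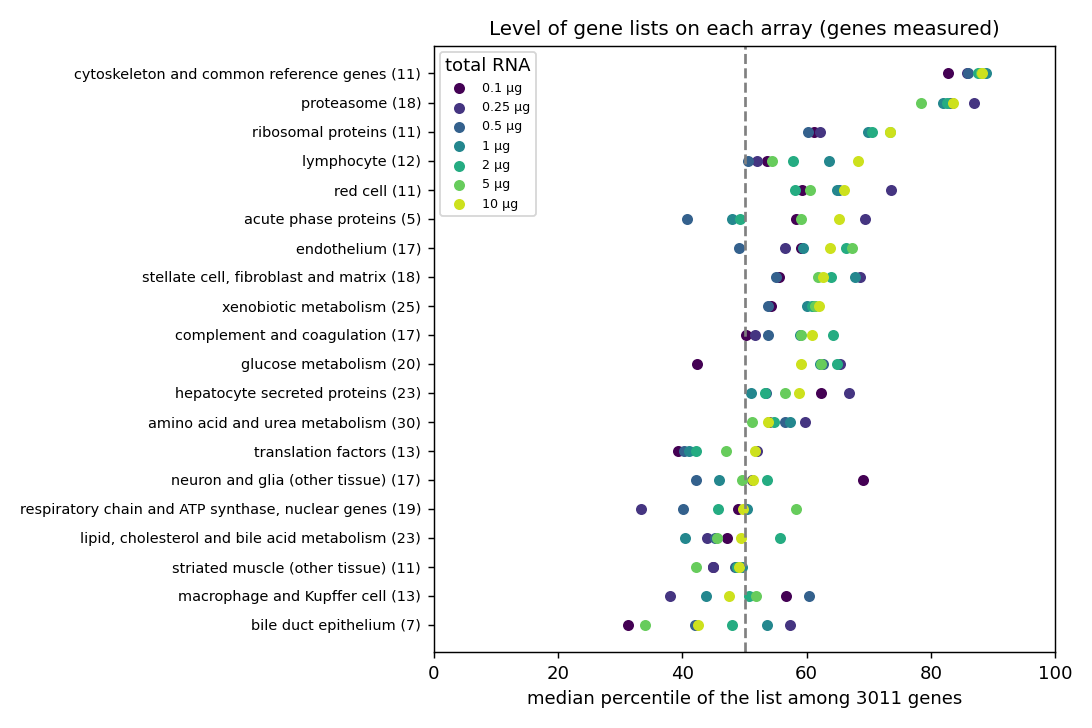
Median signal percentile among 3011 genes (horizontal axis) of the 20 gene lists (vertical axis, measured genes in brackets), with 1 point per array coloured by µg of RNA and a dashed line at the middle. The common reference genes and the proteasome lie at 88.2 and 83.6 at 10 µg, and hepatocyte secreted proteins at 58.8.

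For most named genes the signal read as steeper above 1 µg than below it, but no change of slope passed the test. The probe of LDHA read 11516 at 0.1 µg, 156011 at 1 µg and 4041089 at 10 µg, and that of CYC1, cytochrome c1, read 1938, 4154 and 62478. Over all probes the median fitted slope was 0.27 below 1 µg and 0.87 above it, and among the brightest 10% of probes 1.09 and 1.46. Background left in the signal flattens the slope below 1 µg. The array median was 1629 against a lower percentile of 1 of 1329 at 0.1 µg, and 2989 against 1902 at 1 µg. No change of slope was fitted after subtraction of background, so these medians do not show a weaker response below 1 µg. With all 7 arrays 0 probes became steeper and 0 flatter (limma, Benjamini-Hochberg 0.05, 1958 at an unadjusted p under 0.05). The arrays of 5 and 10 µg decided this count, since 3415 probes became steeper and 7 flatter without 5 µg, and 3608 and 3 without 10 µg. In simulated data of 7 arrays, with noise independent between probes, the test found 28.0% of changes of slope of 1 and 78.0% of changes of 2.

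The brightest probes were largely shared between amounts. Of the 555 probes among the brightest 10% at 0.1 µg, where HNRNPA1 was the brightest of all 5544 at 41454, 507 (91.4%) were also among the brightest 10% at 10 µg, against 10.0% by chance. The share was between 89.2% at 5 µg and 94.2% at 0.5 µg for the others. Over all probes, Spearman correlations of the 21 pairs of arrays ran from 0.491 (0.1 and 0.25 µg) to 0.927 (2 and 10 µg), with a median of 0.676, across probes that are not independent replicates. The array of 10 µg was closer to that of 2 µg than to that of 5 µg (0.880). Among the probes brighter than the median probe, the correlations ran from 0.625 (0.1 and 5 µg) to 0.918 (1 and 2 µg), with a median of 0.755. There the array of 10 µg had 0.911 with that of 2 µg and 0.755 with that of 5 µg.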

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

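Leaving out both 5 and 10 µg, centring or ranking within each of 2 parts of the probe numbers, random lists matched on probes per gene, and brightness classes ranked on 1 array were chosen after the data were seen. The correlation of median signal with amount (0.903 to 0.976 over 10 settings) and of dynamic range (0.755 to 0.990 over 9) kept direction and threshold in each setting run, and so did the 2 lists above random lists (3 settings). Without scaling, 5146 to 5543 probes rose and 0 fell in 11 settings, and 2772 rose among the probes brighter than the median probe, where only 2772 were tested. Relative to the array median, 0 of those brighter probes fell, and 282 fell without 5 and 10 µg, where 5 arrays remained. Quantile normalization left 0 rises and 0 falls, and cyclic loess 0 and 0, of which the cause was not tested. Division by the median absolute deviation gave 4 rises and 389 falls, and it divides the arrays of larger amounts, whose signals spread more widely, by larger numbers. Centring on the 75th percentile gave 856 rises and 3212 falls, since that percentile rose more steeply than the median. Of the 3593 median-centred calls, 1743 were made in the same direction without 5 and 10 µg and 2424 with centring in parts. Leaving out 1 array at a time gave 1638 to 2023 rises and 1358 to 1810 falls, 0 to 3608 probes steeper above 1 µg, 0 to 7 flatter, and 0 to 1 gene lists. The bend calls appeared without 5 µg (3415 steeper, 7 flatter) and without 10 µg (3608 and 3), and 1 list passed without 0.1 µg; the cause was not tested. Without 5 and 10 µg 2 lists passed, of which the cause was not tested. With the median absolute deviation the 10 steepest rises reversed, to -3.18 in HNRNPA1, -2.91 in PSMA5, -2.71 in BTBD1, -2.31 in ELF1, -2.24 in PDE6G, -2.21 in PCDHA6, -1.06 in PRKY, -2.49 in NR4A3, -2.91 in FBXO34 and -2.88 in KANK1, in units of that deviation. Among the 10 steepest rises and 10 steepest falls, cyclic loess turned the sign without passing the test in HNRNPA1 (-0.013), PSMA5 (-0.0024), FBXO34 (-0.029), KANK1 (-0.025) and TDRD3 (0.0054). Of all 98 named genes, 42 had the opposite sign with cyclic loess and 37 with quantile normalization, 0 of them past the test. A floor at the lower percentile of 5 was not run, since no value was at or below 0. No paired analysis was possible because each amount has 1 array. Signal over background limits the dim probes, and their slopes by class differ with the ranking: with classes ranked on the array of 0.1 µg and slopes from the other 6, the dimmest class had a median slope of 0.50 rather than 0.28, and ranked on 10 µg 0.29.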

Other observations

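All tests in this part were chosen after the result was seen, except the counts of probes in both slope fits under reassigned amounts.

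Of 100 assignments of the amounts to the arrays, 1, the real one, gave as many probes past 0.05 without scaling (5537, highest other 5226, median of the others 0). Relative to the array median, 1 of 100 also gave as many (3593, highest other 2635, median of the others 0). The real assignment thus gave the highest count of the 100 in both fits. All probes share the same arrays, with 1 array per amount, so these counts are no separate test for each probe and do not exclude chance. The highest other assignments kept most of the order of the amounts, with rank correlations of 0.857 and 0.750 to the real one. For the change of slope at 1 µg the real count was 0, so that all 100 of 100 assignments gave as many by construction (highest other 4762, median of the others 0), which says nothing about chance.

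Probes assigned to the same accession did not share their signal, with a correlation of -0.0799 over 117 pairs. Noise of dim spots is argued against as the whole cause, because 0% of the 21 pairs with a probe among the brightest 10% had both there (upper 95% bound 16.1%), while 93.9% of the brightest 10% at 2 µg was also among the brightest at 10 µg. Names that are not aligned with the probes over the table remain a candidate explanation: 0 of 20 gene lists passed against rotated names. The proteasome and the reference genes came close (0.0577 each), which leaves a partial alignment open. No biological explanation was tested, and probes of 1 accession that bind woodchuck transcripts differently stay open.

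Adjacent probe numbers shared their signal, with a correlation across probes of 0.425 at a distance of 1, 0.171 at 2 and 0.278 at 95. A slow gradient over the membrane is argued against as the whole cause by -0.0414 at a distance of 5. Neighbours whose symbols differ in their first 3 letters had a correlation of 0.413. Related genes can have such different symbols, and the names may not be aligned with the probes, so this value does not decide on related genes placed side by side. Signal spreading from very bright spots, here the brightest 2% in each part of the probe numbers, was examined in pairs of neighbours that both lay away from them. Over 3248 such pairs the correlation was 0.270 (95% bootstrap interval 0.236 to 0.303), which argues against these spots as the whole cause. These pairs can still lie next to other bright spots, so spreading between spots in general stays open. For very bright spots, 171 dimmer probes next to 112 of them read above other dimmer probes by 0.18 log2 units at 0.1 µg and 2.13 at 10 µg (95% bootstrap interval 1.98 to 2.23), and by 1.49 at a distance of 95. Any cause of the correlation gives such an excess. Slopes of named probes with neighbouring numbers, such as GAPDH (842) and EIF4A1 (843), may then not be independent. No biological explanation was tested.

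From 2 to 5 µg 99.9% of the probes read higher, by a median of 1.82 log2 units, and from 5 to 10 µg 56.5%, by a median of 0.10. Saturation of bright spots is argued against as the whole cause, because after background subtraction 1970 probes of brightness classes 4 to 8, away from very bright ones, differed from 5 to 10 µg by a median of 0.0816 log2 units (95% bootstrap interval 0.0242 to 0.124), against 0.17 in the brightest class. With each array's lowest signal as background the median for these classes was 0.0431 (95% bootstrap interval -0.0062 to 0.0876), against 0.17. The text below uses the lower percentile of 1 as background. For class medians, a single scale factor on 1 array cannot be told apart from a response to the amount, as each amount has 1 array. After subtraction of that percentile the array of 5 µg lay above the line from 2 to 10 µg. The median excess was 0.88 to 1.06 in brightness classes 4 to 10 of 10, a range of 0.179. Single probes scattered about these medians, with interquartile ranges from 0.51 in class 10 to 1.39 in class 8. A scale factor alone leaves that scatter unexplained, and 1 array cannot separate it from noise. Classes 1 to 3 lay at 0.49, 0.81 and 0.85 (range over all classes 0.567), but only 417 of 554 probes of class 1 exceeded the background on the arrays used, so signals near it do not decide. No biological explanation was tested.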
